A study of Mus musculus with 15 samples.

How the data were processed

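The samples were 15 RNA-seq libraries of mouse spinal motor neurons at postnatal day 6, 3 libraries for each of 5 motor pools. A motor pool is the set of motor neurons that supplies 1 muscle. The pools here supplied the tibialis anterior (TA), the extensor digitorum longus (EDL), the peroneus longus (PL), the gastrocnemius (GS) and the intrinsic foot muscles (IF). The last are a group of muscles, whose neurons are called 1 pool here. Per the labels, a fluorescent retrograde tracer (the B subunit of cholera toxin) was injected into muscle at day 4, and traced cells were captured by laser from frozen spinal cord sections of 12 µm. Per the labels, a library pooled 30 to 40 cells from 2 to 5 animals with a captured area of at least 250000 µm2. The labels call the libraries biological replicates, but nothing ties a library to particular animals. Whether libraries of different pools shared an animal is thus not known. The p-values of single genes below are set against the spread between these pooled libraries. Those of the list test camera with its preset correlation, described below, compare the genes of a list with other genes. They do not measure the spread of a list between libraries. Per the labels, cords from injections that were not specific had been discarded. RNA of other cells lying in a captured area can enter a library with that of the neuron.

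Per the labels, cDNA was made with the Ovation RNA-Seq System V2, tagged with Nextera and sequenced with single-end reads on an Illumina HiSeq 2000 to 25 to 30 M reads. Nextera does not mark strand, so reads of a gene and of an overlapping or antisense partner are not separable. The authors deposited raw read counts per gene, and per the submitters' processing notes the reads had been aligned with Bowtie 0.12.9 to the mouse build mm9. The gene counter and the gene model are not given in the sources used here. The count columns held 16 cells below 0 in 4 genes, for which no source gives a reason, and these 4 genes were left out. The RPKM columns, computed by the authors from the same counts, were used only to read the divisor of each library, of which the gene counts made up between 44.1% and 55.0%. The deposited lists of genes higher in one pool than in another held ratios (a fold of mean normalized counts) and p-values, which per the submitters' processing notes came from DESeq, with no version given. The columns of the intrinsic foot pool carry the word foot in the table and were matched to the IF samples by that word and the replicate number.

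The table held 36814 genes, of which 16357 had no read in any library. Total counts per library ran from 4417114 to 8488368. No pair of libraries of one pool agreed within counting noise: the chi-square of their counts was at least 11.4 times its degrees of freedom. Genes were kept by the filterByExpr rule of edgeR, which left 14340 genes. The main test was edgeR's quasi-likelihood F-test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) with TMM scaling, 1 coefficient per pool and all 15 libraries in 1 fit, so that the pools shared 1 estimate of the spread. The common dispersion was 0.789 and the prior degrees of freedom were 8.44. Adjusted p-values are Benjamini-Hochberg values over the 14340 genes of 1 comparison, with a threshold of 0.05. The comparisons were all 5 pools at once, each pool against the mean of the other 4 pool coefficients, and the 10 pairs. A fold against the other 4 pools is thus a difference of mean log levels, not a ratio of mean counts, and a pool near 0 pulls it. Errors of log2 fold changes are standard errors, computed as the log2 fold change over the square root of F. Levels are TMM-scaled CPM, the read counts of a gene per 1e+06 counts of its library, with the SD over 3 libraries. For a group with no read, the fold is a lower bound against 3 counts over the group. For a group with 1 to 3 reads it is a ratio with a 95% counting interval. Both cover counting error only, since PCR copies are not independent molecules. Fitted log2 folds of genes with a pool at 0 depend on the prior count of the fit and are given no size in the comparisons, except under settings that reversed a direction, where such sizes are uncertain. The share of genes whose libraries lie apart by chance holds for unselected genes and is no test of called genes, which were picked on the same libraries.

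Genes were named by a rule fixed before the data were examined. For each pool against the other 4, these were up to 12 genes per direction with the largest change among called genes whose 3 libraries lay apart from the 12 others. For each pair, they were up to 5 per direction among called genes whose 3 libraries did not overlap the other 3. Called members of each gene list were added, up to 6 for each pool by p, or else the 2 members with the smallest p, and so was a fixed set of genes of motor neuron identity. Of that set, Slc18a3 was not analysed here. Clone and model names were counted but not named. The text prints the named genes that bear on each comparison and counts the others. Some named results are not reported here and are left out of the sensitivity counts of named results. Of the 180 named genes, 25 overlap another gene of the table that holds at least 10% as many counts. Among those printed, these are Alas2, Chat, Grin3b, Hoxa3, Hoxa6, Hoxb8, Hoxd10, Hoxd11, Lxn and Pou3f1, the last with 2 identifiers of identical counts. Their values are uncertain for that reason, as are those of Reg3b, Ly6a, Hspa1a, and ribosomal protein genes, whose near-identical relatives can share reads.

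Gene lists were 30 sets fixed before the data were examined: Hox genes and their cofactors, retinoid genes, motor neuron identity, limb transcription factors, cadherins, protocadherins, ephrins, semaphorins, netrin and Slit genes, neurotrophic factors, gamma and alpha motor neuron markers, potassium channels, sodium, calcium and HCN channels, glutamate, GABA and glycine receptors, neuropeptides, axonal injury genes, immediate early genes, copines, markers of 8 other cell types, ribosomal proteins and oxidative phosphorylation. The cell types were astrocytes, oligodendrocytes, microglia, endothelial cells, fibroblasts, red cells, and inhibitory and excitatory interneurons. Several genes stand in more than 1 list, and Lhx1, among the inhibitory interneuron markers, is also a transcription factor of motor neurons. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, a self-contained rotation test, were alternatives. The mean log2 level of each list per library was also compared, 3 libraries of a pool against 12 others, by an exact two-sided permutation test over all 455 splits.

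The steps were tested on 3 sets of simulated counts, each with 200 genes changed in IF by 4-fold or 16-fold in the simulation, on a mean of 13895 tested genes. For IF against the other 4 pools edgeR recovered 180 of 293 genes changed 16-fold (61.4%) and 65 of 291 changed 4-fold (22.3%), with 18 false calls. For TA against IF it recovered 119 of 293 (40.6%) and 22 of 291 (7.56%), with 7 false calls. For the 5 pools at once it recovered 126 of 293 (43.0%) and 31 of 291 (10.7%), with 6 false calls, and for TA against EDL, where nothing was changed, it made 0. DESeq2 1.42.0 recovered 220 and 104 genes for IF against the other 4 pools with 225 false calls, and made 101 false calls for TA against EDL. Limma voom with sample weights recovered 145 and 68 with 34 false calls. A simulated list of 20 genes raised 3-fold was found in 3 of 3 simulations, with 0 calls in 135 tests of unchanged lists. The counts were drawn gene by gene with the spread that edgeR had fitted, the same in every library and with no correlation between genes. They may thus favour edgeR and camera, and do not give error rates for the real libraries.

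The alternatives were no filter on low counts, at least 50 counts in 3 libraries, median-of-ratios size factors, the replicate number as a block, DESeq2, limma voom with sample weights, only the 6 libraries of a pair, and each library left out in turn. Upper-quartile scaling, a robust prior spread and a run without PL replicates 2 and 3 were added after the data had been seen. Coordinates are those of the deposited gene table on mm9. No genome sequence or annotation of that build was used here.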

Results

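RNA from captured motor neurons of 5 hind-limb motor pools of wild-type mice was sequenced at postnatal day 6, with 3 libraries for each pool. The pools supplied the tibialis anterior (TA), the extensor digitorum longus (EDL), the peroneus longus (PL), the gastrocnemius (GS) and the intrinsic foot muscles (IF). The raw gene counts summed to between 4417114 (PL 2) and 8488368 (PL 1) per library. Genes with at least 1 read numbered 16895 ± 371 in IF (SD, n = 3), 14946 ± 1415 in GS, 14915 ± 639 in EDL, 13488 ± 374 in TA and 12252 ± 2554 in PL. PL 2 and PL 3 stood apart with 11019 and 10548 such genes and with 25.7% and 29.2% of the tested genes at 0, against 0.732% to 13.7% in the 13 other libraries. Rank correlations of the counts within a pool were 0.945 to 0.947 in IF and 0.812 to 0.838 in PL. Levels below are TMM-scaled CPM, given as mean ± SD of 3 libraries, and errors of log2 fold changes are standard errors. Each library pooled cells of 2 to 5 animals per the labels, and nothing ties a library to particular animals.

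**Figure D1:**
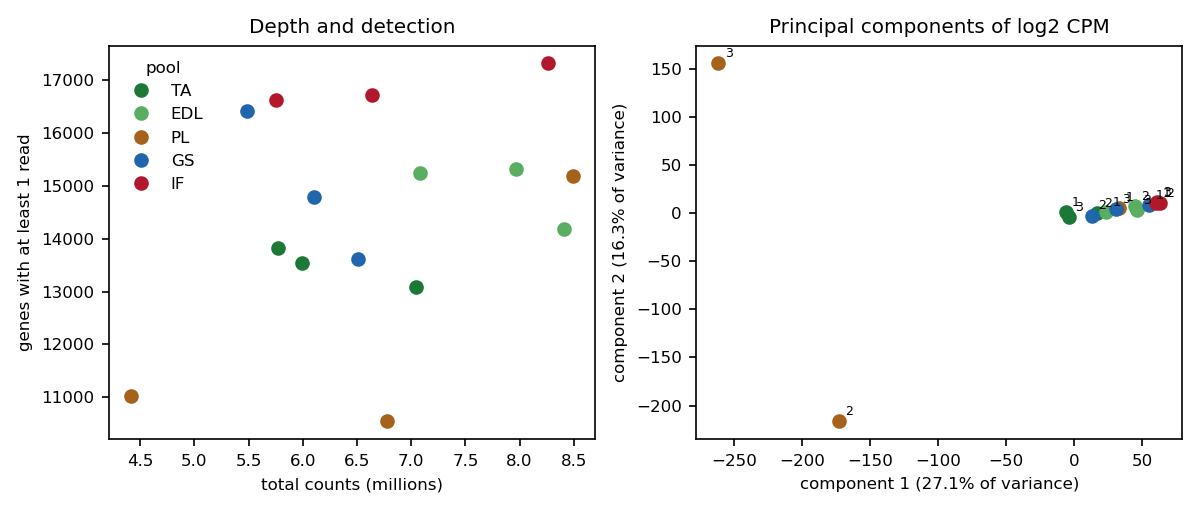
Left, total gene counts (M) against genes with at least 1 read for the 15 libraries, coloured by pool. Right, the first and second principal components of log2 CPM, which held 27.1% and 16.3% of the variance, where PL 2 and PL 3 lay apart from the 13 others.

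Among the genes that differed across the 5 pools were precursors of peptides, retinoid genes, transcription factors and an adhesion molecule. Nts, the precursor of neurotensin, was at 514 ± 74.5 CPM in EDL, 233 ± 18.2 in PL, 36.6 ± 14.4 in GS, 32.8 ± 11.3 in TA and 3.95 ± 1.51 in IF. Sst, the precursor of somatostatin, was at 1761 ± 734 CPM in GS, 921 ± 157 in TA, 359 ± 95.5 in IF, 90.8 ± 55.9 in PL and 73.9 ± 29.9 in EDL. Isl1, a LIM homeodomain factor of medial lateral motor column neurons, was at 97.1 ± 19.6 CPM in IF and 66.1 ± 24.3 in GS, while the 9 libraries of TA, EDL and PL held 5 reads, all in EDL. Alcam, a cell adhesion molecule, was at 1028 ± 184 CPM in PL, 702 ± 25.0 in TA, 665 ± 291 in EDL, 147 ± 25.8 in GS and 135 ± 21.7 in IF. The edgeR quasi-likelihood F-test for any difference among the pools gave Benjamini-Hochberg adjusted p = 1.09e-06 for Nts, 4.91e-06 for Aldh1a2, 2.94e-05 for Sst, 0.000104 for Alcam, 0.000138 for Crabp2, 0.000227 for Isl1, 0.000470 for Calca, 0.00134 for Hoxc10, 0.00152 for Cpne4 and 0.00320 for Vip. It passed 188 of 14340 genes, and 2222 had an unadjusted p under 0.05. The count was 66 without IF 2 and 1211 without PL 1, and 9 of the 15 libraries moved it by more than 1.5 times when left out.

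On mm9, Nts (ENSMUSG00000019890) lies on chromosome 10 from 101944394 to 101953053, and Vip (ENSMUSG00000019772) on the same chromosome from 4698927 to 4707324. Aldh1a2 (ENSMUSG00000013584) lies on chromosome 9 from 71063596 to 71144051, and Cpne4 (ENSMUSG00000032564) on the same chromosome from 104449616 to 104936875. Sst (ENSMUSG00000004366) lies on chromosome 16 from 23889667 to 23890931, and Alcam (ENSMUSG00000022636) on it from 52249109 to 52454188. Crabp2 (ENSMUSG00000004885) lies on chromosome 3 from 87752588 to 87757299, and Isl1 (ENSMUSG00000042258) on chromosome 13 from 117088478 to 117099897. Hoxc10 (ENSMUSG00000022484) lies on chromosome 15 from 102797223 to 102802145, and Calca (ENSMUSG00000030669) on chromosome 7 from 121774994 to 121779872. Of the genes of motor neuron identity named in advance, Pou3f1, Fign and Chat also passed the edgeR quasi-likelihood F-test, with Benjamini-Hochberg adjusted p = 0.0150, 0.0163 and 0.0245. Lhx1, Hoxd11, Hoxc8, Esrrg, Rbfox3, Etv4, Nkx6-1, Hoxd10, Mnx1 and Runx1 did not pass it, with Benjamini-Hochberg adjusted p from 0.0605 for Lhx1 to 0.874 for Runx1. Esrrg, a marker of gamma motor neurons, was between 206 ± 43.7 CPM in EDL and 503 ± 122 in GS, and Rbfox3, a marker of alpha motor neurons, between 139 ± 30.0 in IF and 406 ± 225 in TA.

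**Figure D2:**
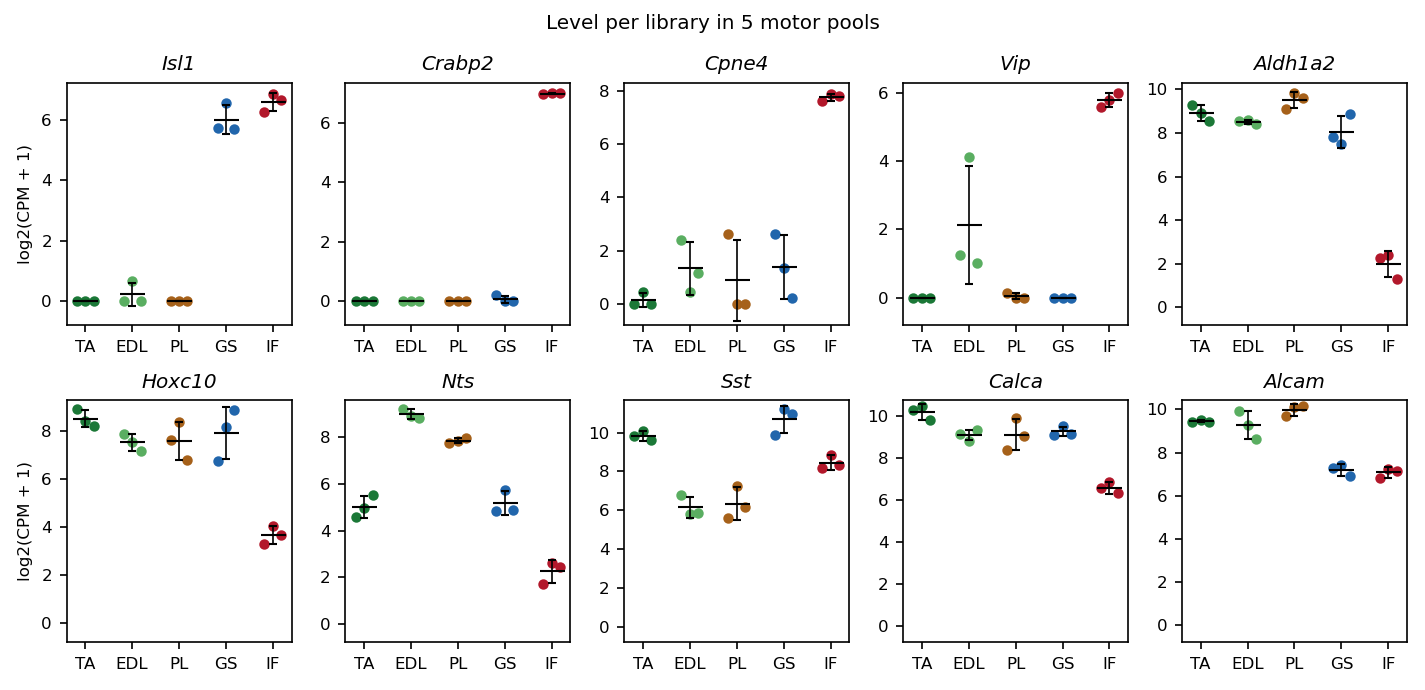
Level of 10 genes in the 5 pools as log2(CPM + 1), with a point for each library, a bar for the mean and an error bar for the SD (n = 3). Isl1 was above 0 in GS and IF and at 5 reads in the 9 libraries of TA, EDL and PL together.

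The comparison of the intrinsic foot pool with the other 4 asked what sets apart the neurons of the foot's own muscles. Retinoid genes went opposite ways. Crabp2, a retinoic acid binding protein, was at 124 ± 1.93 CPM in IF and at 1 read in the 12 other libraries, a ratio of 9742 with a counting interval of 1748 to 384770. Aldh1a2, which makes retinoic acid, was at 3.20 ± 1.54 CPM in IF against 292 ± 159 in GS and 746 ± 184 in PL, and fell by 7.10 ± 0.51 on the log2 scale. Reg3b, a secreted lectin, was at 84.3 ± 28.0 CPM in IF and had no read elsewhere, so it was at least 2201-fold higher. Cpne4, a copine, was at 218 ± 19.7 CPM in IF and at most 2.27 ± 2.56 in another pool, and it was the 1 of 9 copines called. Among other genes higher in IF, Vip, the precursor of vasoactive intestinal peptide, was at 55.2 ± 8.01 CPM against 6.27 ± 8.78 in EDL, and the POU factor Pou3f1 was at 22.6 ± 0.410. Tac1, the precursor of substance P, was at 63.2 ± 17.1 CPM against 8.05 ± 10.8 in GS, and the cytokine receptor Lifr was at 1392 ± 109 (log2 fold change 1.99 ± 0.23). Lower in IF were Nts (-4.79 ± 0.45), the Hox gene Hoxc10 (-4.41 ± 0.52), the transcription factor Sox6 (-3.70 ± 0.54), the Hox cofactor Meis2 (-3.63 ± 0.63), Calca, the precursor of calcitonin gene-related peptide (-2.88 ± 0.33), and the semaphorin receptor Plxna2 (-2.64 ± 0.40). In the edgeR quasi-likelihood test, the Benjamini-Hochberg adjusted p was 3.91e-07 for Aldh1a2, 9.33e-06 for Crabp2 and Nts, 5.15e-05 for Isl1, 8.78e-05 for Cpne4, Lifr and Calca, 9.76e-05 for Reg3b, 0.000101 for Hoxc10, 0.000238 for Vip, 0.00201 for Pou3f1 and Plxna2, 0.00457 for Tac1 and 0.00675 for Meis2. It called 158 genes for IF, 101 higher and 57 lower, of which 75 and 50 had all 3 IF libraries apart from the 12 others, where chance gives 1 in 455 for a direction among unselected genes. The count was 31 without IF 3 and 333 without PL 1, 7 libraries moved it by more than 1.5 times, and 15 of the 23 genes named by size kept their call without each single library. Meis2 lost its call without IF 1 or IF 3. The majority direction turned without PL 2 and PL 3, with 77 higher and 79 lower, and by DESeq2, with 94 and 155, while limma voom gave 908 and 597.

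Neurotrophic factor genes had 3 members higher of 25 in IF, and adjusted over the list alone 6 were higher and 2 lower. Neuropeptide precursors in IF had 4 members higher and 4 lower of 22, and adjusted over the list alone 6 were higher and 4 lower. The same list had 2 higher in TA, 1 higher and 1 lower in EDL and in GS, and 4 higher and 1 lower in PL. Adjusted over the list alone 11 passed in TA, 5 in EDL, 4 in GS and 6 in PL, so its calls were not particular to IF. Of 62 potassium channel genes 1 was higher and 7 were lower, among them Kcna1 (-1.48 ± 0.27) and Kcnk3 (-2.10 ± 0.42), and adjusted over the list alone 3 were higher and 8 lower. Camera put potassium channels lower in IF (Benjamini-Hochberg adjusted p = 0.00742; adjusted p = 0.155 with an estimated correlation). Motor neuron identity genes (1 higher, 1 lower of 19; list alone 1 and 4) were lower by camera with Benjamini-Hochberg adjusted p = 0.0152, and adjusted p = 0.245 with an estimated correlation. Alpha motor neuron markers, with Calca called of 13 and 3 lower adjusted over the list alone, had camera Benjamini-Hochberg adjusted p = 0.0125, and adjusted p = 0.155 with an estimated correlation. Sodium, calcium and HCN channels (1 higher, 2 lower of 36; list alone 1 and 3) had camera Benjamini-Hochberg adjusted p = 0.0263, and adjusted p = 0.298 with an estimated correlation. Glutamate, GABA and glycine receptors (1 lower of 38, the glycine receptor Glra1; list alone 1) had camera Benjamini-Hochberg adjusted p = 0.0377, and adjusted p = 0.245 with an estimated correlation. Markers of oligodendrocytes, the cells that make myelin, lay below the other pools in all 16 tested members, with a median log2 fold change of -1.53. Mbp, at 68.7 ± 19.6 CPM in IF, which codes for a myelin protein, was among those called, and 4 were lower adjusted over the list alone. Camera gave Benjamini-Hochberg adjusted p = 1.16e-06 for these markers, and adjusted p = 0.119 with an estimated correlation. Of 65 ribosomal protein genes 54 lay above the other pools, with a median of 0.62, but 0 were called over all genes or adjusted over the list alone; camera gave Benjamini-Hochberg adjusted p = 7.59e-05, and adjusted p = 0.404 with an estimated correlation. When PL 2 and PL 3 were left out, 3 of the 7 lists no longer passed camera in IF, with Benjamini-Hochberg adjusted p = 0.0929 for motor neuron identity genes, 0.0886 for sodium, calcium and HCN channels and 0.129 for the receptors.

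In the tibialis anterior pool, Rxfp1, a relaxin receptor, was at 18.1 ± 14.2 CPM and at 1 read in the 12 other libraries, a ratio of 1557 with a counting interval of 279.55 to 61519. Sostdc1, a secreted antagonist of bone morphogenetic proteins, was at 47.6 ± 36.7 CPM in TA, 12.4 ± 2.40 in GS and 0 in EDL, and Kcng1, a potassium channel subunit, was at 56.1 ± 63.4 in TA and 0 in PL. Vstm2a (2.38 ± 0.26) and Parm1 (1.67 ± 0.23) were also higher, as were Aldh1a2 (1.96 ± 0.28), Sst (1.85 ± 0.30), Hoxc10 (1.78 ± 0.34) and Calca (1.67 ± 0.24). The fold of Aldh1a2 was drawn up by the low level of IF, since TA was at 493 ± 122 CPM and PL at 746 ± 184, and Sst was higher still in GS. A low level of IF drew up the folds of Hoxc10 and Calca too. Hoxc10 was at 11.9 CPM in IF, 369 in TA and 285 in GS, and its TA libraries did not lie apart from the others. Calca was at 96.1 CPM in IF, 1199 in TA and 621.5 in GS. Lower in TA were the heparan sulfate enzyme Hs3st4 (-5.20 ± 0.73), the netrin receptor Unc5d (-4.16 ± 0.66), Clip4 (-3.21 ± 0.52), Lxn (-3.08 ± 0.44) and the adhesion molecule Negr1 (-2.34 ± 0.32). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 0.000424 for Vstm2a, 0.00234 for Parm1, Kcng1, Hs3st4 and Negr1, 0.00241 for Aldh1a2 and Calca, 0.00256 for Sostdc1, 0.00508 for Rxfp1, 0.00526 for Sst, Unc5d and Clip4, and 0.0229 for Hoxc10. It called 60 genes for TA, 41 higher and 19 lower, of which 18 and 14 had all 3 TA libraries apart from the others, where chance gives 1 in 455 for a direction among unselected genes. The count was 22 without IF 1 and 246 without PL 1, 13 libraries moved it by more than 1.5 times, and it was 236 without PL 2 and PL 3. By DESeq2 more were lower, with 143 higher and 277 lower. Of the 24 genes named by size 9 kept their call without each single library. Sst lost its call without TA 2, and Hoxc10 lost it without any 1 of TA 1, TA 2, TA 3, EDL 2, EDL 3, IF 1 and IF 3.

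Oligodendrocyte markers in TA lay above the other pools in 15 of 16 tested members, with Mog called (17.98 ± 22.0 CPM in TA, no read in EDL) and 5 higher adjusted over the list alone. Camera gave Benjamini-Hochberg adjusted p = 1.32e-05, and adjusted p = 0.152 with an estimated correlation. Potassium channels lay above in 44 of 62 members, with Kcng1 called and 5 higher adjusted over the list alone; camera gave Benjamini-Hochberg adjusted p = 0.0299, adjusted p = 0.206 with an estimated correlation and 0.0903 without PL 2 and PL 3. The mean level of the oligodendrocyte markers per library was 1.52 higher in TA on the log2 scale than in the 12 others (exact two-sided permutation p = 0.00220, adjusted 0.0824). Cadherins in TA (-0.682) had the same p and adjusted p in that test. So did neuropeptide precursors (1.01) and neurotrophic factor genes (0.803) in IF. Potassium channels were 0.386 higher in TA (permutation p = 0.0527, adjusted 0.283).

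The extensor digitorum longus pool was set apart by Nts, at 514 ± 74.5 CPM (log2 fold change 3.99 ± 0.27), and by a low level of Foxp1, a transcription factor of limb motor neurons, at 16.2 ± 6.96 CPM against 122 ± 76.9 in PL and 199 ± 19.3 in IF (-3.27 ± 0.49). Ly6a, a surface antigen, was at 158 ± 122 CPM (5.27 ± 0.57), and Dcn, the matrix proteoglycan decorin, at 118 ± 67.8 (5.91 ± 0.92). Lower were Ndst4, a heparan sulfate enzyme (-3.73 ± 0.62), Sst (-2.70 ± 0.40) and Fgf13 (-1.69 ± 0.31). Of 7 markers of fibroblasts and meninges Dcn was called, and 4 were higher adjusted over the list alone; camera gave Benjamini-Hochberg adjusted p = 0.0170, adjusted p = 0.256 with an estimated correlation and 0.113 without PL 2 and PL 3. Of 25 neurotrophic factor genes 0 were called in EDL over all genes or adjusted over the list alone, and camera put them lower with Benjamini-Hochberg adjusted p = 0.0256, and adjusted p = 0.155 with an estimated correlation. By edgeR quasi-likelihood, the Benjamini-Hochberg adjusted p was 1.91e-07 for Nts, 0.000170 for Ly6a, 0.00826 for Foxp1 and Sst, 0.00899 for Dcn, 0.0172 for Ndst4 and 0.0360 for Fgf13. It called 14 genes for EDL, 9 higher and 5 lower, 5 and 3 of them with all EDL libraries apart from the others, where chance gives 1 in 455 for a direction among unselected genes. The count was 2 without EDL 2 and 25 without PL 1, and 8 libraries moved it by more than 1.5 times. By DESeq2 more were lower, with 32 higher and 37 lower. Of the 7 genes named by size, Ly6a and Nts kept their call without each single library. Without EDL 2 the calls of Dcn, Foxp1, Ndst4, Sst and Fgf13 were lost. Foxp1 and Ndst4 were also lost without EDL 1, and Sst without EDL 3. Fgf13 was also lost without any 1 of TA 2, TA 3, EDL 1, EDL 3, GS 2, GS 3, IF 1, IF 2 and IF 3.

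In the peroneus longus pool, Glp1r, the receptor of glucagon-like peptide, was at 286 ± 217 CPM against 5.75 ± 7.36 in EDL and 0 in TA. Plxna2 was at 840 ± 441 CPM against 355 ± 9.43 in EDL, the next highest pool (log2 fold change 2.72 ± 0.29). Aldh1a2 (2.71 ± 0.28), Nts (2.56 ± 0.28, below its level in EDL), the granin Scg2 (1.95 ± 0.25) and Chat, the enzyme that makes acetylcholine (1.73 ± 0.29, at 405 ± 142 CPM), were higher too, and Sst (-2.33 ± 0.39) and the RNA-binding protein Raly (-5.83 ± 1.04) lower. The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 0.000107 for Plxna2 and Aldh1a2, 0.000126 for Nts, 0.000450 for Glp1r, 0.000490 for Scg2, 0.00304 for Chat and Sst, and 0.00507 for Raly. It called 698 genes for PL, 646 higher and 52 lower, of which 53 and 33 had all 3 PL libraries apart from the 12 others, where chance gives 1 in 455 for a direction among unselected genes. Without PL 2 and PL 3, the libraries with few detected genes, the count was 10, with 8 higher and 2 lower, and Glp1r was the 1 of the 24 genes named by size that kept its call. Aldh1a2, Nts and Sst kept theirs too, while Plxna2, Scg2, Chat and Raly lost theirs. The count was 360 without IF 2 and 3210 without PL 1, and 6 libraries moved it by more than 1.5 times.

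By list, PL had 4 of 15 cadherins higher (5 adjusted over the list alone), 2 of 36 sodium, calcium and HCN channels (4), 5 of 38 glutamate, GABA and glycine receptors (8) and 2 of 19 motor neuron identity genes (4), with none lower in either count. Examples were Cdh8, Cacna1e (1.46 ± 0.31), Glra1 (1.78 ± 0.31) and Chat. Camera gave Benjamini-Hochberg adjusted p = 0.0299, 0.00867, 0.0263 and 0.0492 for these 4 lists. They had adjusted p = 0.166, 0.206, 0.206 and 0.404 with an estimated correlation. By the exact two-sided permutation test of list levels per library, PL differed by 0.585, 0.107, 0.116 and 0.165 for them. The permutation p was 0.0242, 0.495, 0.387 and 0.433, with 0.191 the adjusted value for the cadherins. Potassium channels in PL had 8 higher and 1 lower of 62 (9 and 6 adjusted over the list alone), a median log2 fold change of 0.43 and a mean of -0.26, so that the sign depended on the summary. When PL 2 and PL 3 were left out, which left PL 1 alone, the 4 lists no longer passed camera in PL. Motor neuron identity genes then turned lower, and the 3 other lists stayed higher. Ribosomal protein and oxidative phosphorylation genes passed instead, both lower in PL. Of the 58 members of any list called in PL 4 then kept their call, among them Cdh8, while Chat, Cacna1e and Glra1 lost theirs, and 13 changed direction. Single libraries carried some calls: Cdh8 was at 69.1 CPM in PL 1, 4.47 in PL 2, 8.38 in PL 3 and 60.95 in GS 2. The cadherin Cdh5 was at 662 in PL 2, 5.31 in PL 1 and 4.63 in PL 3. Cdh8 lost its call without PL 1, and Cdh5 and Cacna1e without PL 2.

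**Figure D3:**
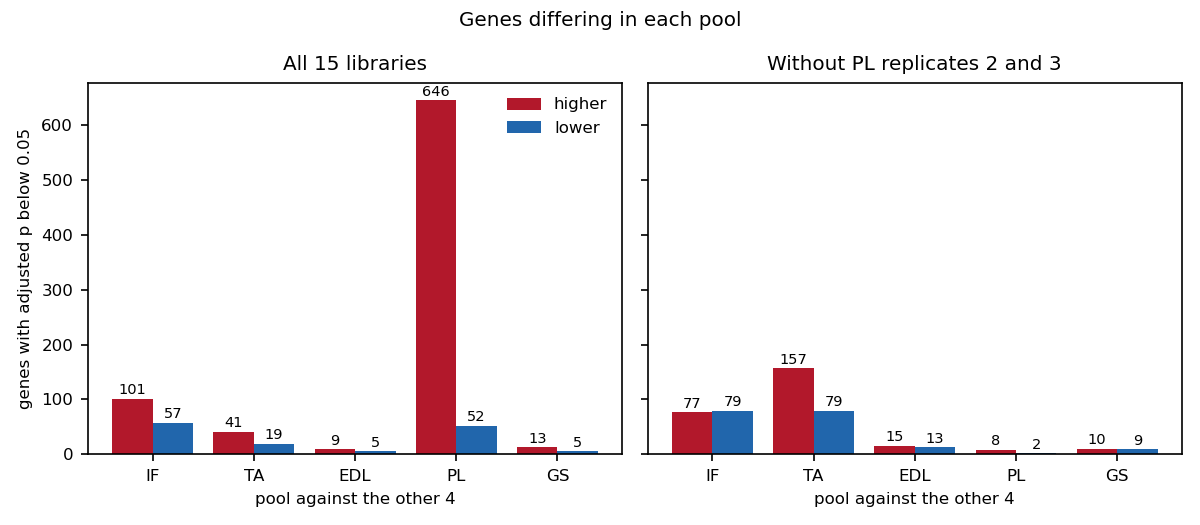
Genes called higher and lower for each pool against the other 4 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), as bars that start at 0. Left, all 15 libraries, where PL had 646 higher and 52 lower; right, without PL 2 and PL 3, where it had 8 and 2.

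In the gastrocnemius pool, Sst was at 1761 ± 734 CPM (log2 fold change 3.02 ± 0.29), with TA next at 921 ± 157. Isl1 was called too, at 66.1 ± 24.3 CPM, but it was higher in IF, and its fold was drawn up by TA, EDL and PL near 0. Lower in GS were Scg2 (-1.93 ± 0.32), the surface protein Cd24a (-1.99 ± 0.35) and Cacna2d1, a calcium channel subunit (-1.91 ± 0.35). Scg2 was about as low in IF, at 102.3 ± 20.15 CPM against 97.04 ± 35.81 in GS, so its low level was not particular to GS. Hsd17b14, Drd1a and Cdh17 were at 11.1 ± 16.1, 10.1 ± 11.5 and 8.07 ± 5.78 CPM, Hsd17b14 with a ratio of 310.8 and a counting interval of 106.35 to 1507. Axonal injury genes lay below the other pools in 10 of 15 members with 0 called over all genes or adjusted over the list alone, and alpha motor neuron markers above in 12 of 13, also with 0 called. Camera gave Benjamini-Hochberg adjusted p = 7.59e-05 and 0.0112 for them, and adjusted p = 0.119 and 0.155 with an estimated correlation. Inhibitory interneuron markers, a list that holds Sst, had 1 of 10 called (3 adjusted over the list alone, 2 higher and 1 lower), with camera Benjamini-Hochberg adjusted p = 0.0232, and adjusted p = 0.161 with an estimated correlation. In the edgeR quasi-likelihood test, the Benjamini-Hochberg adjusted p was 4.16e-05 for Sst, 0.000371 for Isl1, 0.0245 for Scg2, 0.0378 for Cd24a and 0.0411 for Cacna2d1. It called 18 genes for GS, 13 higher and 5 lower, 3 and 2 of them with all GS libraries apart from the others, where chance gives 1 in 455 for a direction among unselected genes. The count was 2 without GS 2, GS 3, IF 2 or IF 3 and 34 without PL 1, and 13 libraries moved it by more than 1.5 times. By DESeq2 more were lower, with 26 higher and 31 lower. Sst and Isl1 kept their call without each library, but 0 of the 5 genes named by size (Hsd17b14, Drd1a, Cdh17, Cd24a and Cacna2d1) did. Scg2 lost its call without any 1 of GS 1, GS 2, GS 3, IF 2 and IF 3.

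Between pairs of pools not holding IF, TA and EDL differed in Sst (3.64 ± 0.46), Foxp1 (3.26 ± 0.54) and Nts (-3.97 ± 0.45), and Sostdc1 was at least 403.3-fold higher in TA. TA and PL differed in Trhr, the receptor of thyrotropin-releasing hormone (3.74 ± 0.61), and Hs3st4 (-5.68 ± 0.78), and Glp1r was at least 1634-fold higher in PL. TA and GS differed in the adhesion molecules Ncam2 (2.40 ± 0.30) and Alcam (2.26 ± 0.33), and Isl1 was at least 377-fold higher in GS. EDL and PL differed in Ly6a (8.28 ± 1.15) and Pcp4l1 (-4.46 ± 0.59). EDL and GS differed in Nts (3.81 ± 0.45), Alcam (2.18 ± 0.32) and Sst (-4.58 ± 0.48). PL and GS differed in Plxna2 (3.38 ± 0.45) and Sst (-4.28 ± 0.48), and Isl1 was at least 372-fold higher in GS. The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p between 0.000238 (Sst, EDL against GS) and 0.0293 (Sostdc1, TA against EDL) for these genes. It called 13 genes between TA and EDL (6 higher in TA), 33 between TA and PL (9 higher in TA), 9 between TA and GS (5 higher in TA), 7 between EDL and PL (2 higher in EDL), 10 between EDL and GS (4 higher in EDL) and 17 between PL and GS (12 higher in PL). In all of them the 3 libraries of the pools did not overlap, for which chance gives 1 in 10 unselected genes.

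These counts moved with single libraries. TA against EDL had 2 without EDL 2 and 32 without PL 3, and TA against GS 2 without TA 1 and 21 without PL 3. EDL against GS had 3 without GS 2 and 20 without PL 3. Without PL 1, TA against PL had 1800, EDL against PL 1778 and PL against GS 1646. EDL against PL had 0 calls without EDL 2, and PL against GS 6 without GS 3. Without PL 2 and PL 3, the counts were 70 for TA against EDL, 39 for TA against GS, 31 for EDL against GS and 2 for EDL against PL, and Plxna2 lost its call between PL and GS, Trhr and Glp1r between TA and PL, and Ly6a and Pcp4l1 between EDL and PL. The libraries that moved a count by more than 1.5 times numbered 11 for TA against EDL, 3 for TA against PL, 3 for TA against GS, 4 for EDL against PL, 6 for EDL against GS and 11 for PL against GS. Sst and Nts between TA and EDL and between EDL and GS, Trhr and Hs3st4 between TA and PL, Ncam2 between TA and GS, and Plxna2, Sst and Isl1 between PL and GS kept their calls without each single library. With only the 6 libraries of a pair, though, PL against GS had 0 calls and TA against PL had 1. Plxna2, Sst and Isl1 between PL and GS thus lost theirs there, as did at least 1 of Trhr and Hs3st4. Ly6a and Pcp4l1 lost their calls without EDL 2. So did Glp1r between TA and PL without TA 1, TA 2 or TA 3 and Isl1 between TA and GS without TA 1. Alcam lost its call without GS 3 for TA and GS and without EDL 1, GS 2 or GS 3 for EDL and GS. Between TA and EDL, both Foxp1 and Sostdc1 lost theirs without any 1 of TA 1, EDL 1, EDL 2, EDL 3, IF 1, IF 2 and IF 3, Foxp1 also without TA 2 and Sostdc1 also without GS 3.

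Each other pool differed from IF in Aldh1a2, by 7.25 ± 0.53 for TA, 6.82 ± 0.52 for EDL, 7.85 ± 0.54 for PL and 6.50 ± 0.51 for GS. Hoxc10 was higher in TA (4.95 ± 0.57) and GS (4.57 ± 0.56) than in IF, and Nts was higher in EDL (7.02 ± 0.52) and GS (3.21 ± 0.44). Crabp2 was at least 710-fold lower in TA, 1055-fold lower in EDL and 701-fold lower in PL, and Isl1 at least 554-fold lower in TA and 547-fold lower in PL. Chrna3, a nicotinic receptor subunit, was at 61.8 ± 7.26 CPM in IF and at 2 reads in EDL, a ratio of 785.8 with a counting interval of 217.5 to 6489, and it lost its call without any 1 of the libraries of EDL or IF. Lxn, a carboxypeptidase inhibitor whose counts overlap those of Gfm1, was lower in GS (-3.93 ± 0.50). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 5.72e-07, 5.93e-07, 2.28e-07 and 2.10e-06 for Aldh1a2 in these pairs. It called 90 genes between TA and IF (55 higher in TA), 29 between EDL and IF (15 higher in EDL), 129 between PL and IF (109 higher in PL) and 18 between GS and IF (10 higher in GS), all with libraries that did not overlap, for which chance gives 1 in 10 unselected genes. Left-out libraries moved them from 36 (IF 2) to 188 (PL 3), from 15 to 44 (PL 3), from 22 (IF 3) to 1986 (PL 1) and from 7 to 39 (PL 3), and 5, 7, 6 and 7 libraries did so by more than 1.5 times. Without PL 2 and PL 3 they were 454, 68, 24 and 77.

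Of the other lists, 0 passed camera in any pool, while fry passed limb transcription factors in IF and TA, netrin and Slit genes in TA and retinoid genes in PL. Hox genes had Hoxc10 and Hoxb8 called in IF, Hoxc10 in TA and Hoxa6, Hoxa9 and Hoxa3 in PL of 30 (adjusted over the list alone 4, 7 and 4). Hox cofactors had Meis2 called in IF and Foxp1 in EDL of 12 (2 and 2 adjusted over the list alone). Retinoid genes had 2 called in IF, 1 in TA and 3 in PL of 20 (4, 2 and 7 adjusted over the list alone), and limb transcription factors 3 in IF, 2 in TA, 1 in EDL, 4 in PL and 1 in GS of 40 (8, 3, 2, 6 and 8). Semaphorins and plexins had 1 lower in IF and 4 higher in PL of 29 (2 and 4 adjusted over the list alone), netrin and Slit genes 1 higher in IF, 1 lower in TA and 6 higher in PL of 31 (2, 1 and 9), ephrins and their receptors Epha3 in IF and Efnb1 in PL of 17 (1 and 1), and protocadherins 2 in PL of 11 (4). Efnb1 was at 348 CPM in PL 2, 0.650 in PL 1 and 0.221 in PL 3, and its log2 fold change was -0.52 without PL 2. Of the members of these lists called in PL, Aldh1a2 alone kept its call without PL 2 and PL 3, and Crabp1, a retinoid gene called higher, was then at -2.78. Gamma motor neuron markers had 0 of 9 called in any pool by edgeR (Plch1 in GS had the smallest Benjamini-Hochberg adjusted p = 0.0850), immediate early genes 0 of 13 (Hspa1a in IF, 0.123), microglia markers 0 of 11 (C1qb in PL, 0.0679), red cell markers 0 of 4 (Alas2 in PL, 0.0886), excitatory interneuron markers 0 of 4 (Reln in IF, 0.0556) and oxidative phosphorylation genes 0 of 74 (Atp5e in PL, 0.0524). Adjusted over the list alone, gamma markers had 1 in TA, 1 in EDL and 2 in GS. Immediate early genes had 2 in IF, red cell markers 1 in PL, excitatory interneuron markers 1 each in IF, TA and GS, and microglia markers and oxidative phosphorylation genes 0 in any pool. In pools where a list had 0 called over all genes, members that passed over the list alone were 2 Hox genes in GS, 1 Hox cofactor in TA and 2 in PL, 1 retinoid gene in EDL and 3 in GS. They were also 2 semaphorin and plexin genes in EDL and 1 in GS, 3 netrin and Slit genes in EDL, 2 protocadherins in IF, 2 astrocyte markers in TA and 1 endothelial marker in EDL. Others were 1 copine in TA and 1 in EDL, 1 cadherin in EDL and 3 in GS, 2 neurotrophic factor genes in TA and 1 in GS, and 1 potassium channel in EDL and 1 in GS. The last were 3 glutamate, GABA and glycine receptors in TA and 1 in GS, 1 axonal injury gene in TA, 2 fibroblast markers in GS and 1 inhibitory interneuron marker in IF. Called members in pools not named so far, with the count adjusted over the list alone in brackets, were 1 motor neuron identity gene in TA (1) and 1 in GS (1), 1 cadherin in IF (4) and 1 in TA (4), 1 sodium, calcium or HCN channel in TA (6) and 1 in GS (1), 1 alpha marker in TA (1) and 3 neurotrophic factor genes in PL (6). There were also 2 axonal injury genes in IF (4), 1 in EDL (2) and 1 in PL (1), 2 oligodendrocyte markers in PL (2), 1 fibroblast marker in IF (1), 2 ribosomal protein genes in PL (0), and 1 inhibitory interneuron marker in TA (1), 1 in EDL (1) and 3 in PL (4). Astrocyte markers had Slc1a2, a glutamate transporter that neurons also transcribe, lower in IF (-0.98 ± 0.22) of 14 (1 adjusted over the list alone), and endothelial markers Rgs5 and Cdh5 higher in PL of 14 (3), both lost without PL 2 and PL 3. The exact permutation test of list levels per library, 3 against 12, gave p under 0.05 in 25 of 150 comparisons. The adjusted p was under 0.05 in 0, with 0.00220 the smallest p and 0.0824 its adjusted value. That p is the smallest the 455 splits can give, so over 150 comparisons the test had little room to pass any. The 0 is thus no evidence that list levels were alike.

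The deposited lists, which were chosen on these libraries, held 534 entries over 16 directed pairs, each a gene given as higher in 1 pool than in another. A gene can stand in several. Of the 514 entries that were tested here all 514 had the same direction, and 153 (29.8%) passed. The edgeR quasi-likelihood test made 328 calls for the same directed pairs, of which 175 were not listed. The lists ended at other thresholds by pair, with a largest adjusted p from 0.00654 to 0.0382 and a lowest listed mean from 28.3 to 306 normalized counts. The 175 thus do not compare like with like. The number that passed was 86 without IF 1 or IF 3 and 246 without PL 1, 4 libraries moved it by more than 1.5 times, and it was 245 without PL 2 and PL 3.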

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

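Upper-quartile scaling, a robust prior spread, the runs without PL 2 and PL 3, leaving out libraries for the list levels and all alternatives for the submitters' lists were chosen only after the data had been seen; the other tests were planned. Values are counts of genes with an adjusted p under 0.05. Alternatives with other pseudocounts were not run, because the table holds counts. Replicate numbers did not pair the libraries: after removal of pool means, libraries of 1 number had correlations from -0.068 to 0.128, and 6 of 15 libraries were closest to their own number. Where no reason is given, the cause was not tested.

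With no filter on low counts the 5 pools at once gave 1425 genes, IF 514, TA 492, EDL 238, PL 1485 and GS 171. Pairs then gave 74 (TA and EDL), 545 (TA and PL), 55 (TA and GS), 242 (TA and IF), 355 (EDL and PL), 40 (EDL and GS), 63 (EDL and IF), 340 (PL and GS), 599 (PL and IF) and 76 (GS and IF), and 392 entries of the submitters' lists passed. The stricter filter gave 63 for TA and PL, median-of-ratios size factors 55, and the robust prior spread 55. Upper-quartile scaling gave 350 for PL (319 higher, 31 lower) and 70 for PL and IF (51 higher in PL, 19 lower), with a median log2 change of all genes of 0.231 in IF and -0.219 in PL.

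With the replicate number as a block, the counts were 95 for the 5 pools at once, 96 for IF, 33 for TA, 7 for EDL, 143 for PL, 6 for GS, 4 for TA and EDL, 11 for PL and GS and 79 for PL and IF.

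DESeq2 made 225 false calls for IF on counts simulated with edgeR's own fitted spread, where edgeR made 18. This does not give their error rates on the real libraries. There DESeq2 gave 1163 genes for the 5 pools at once, 249 for IF (94 higher, 155 lower) and 420 for TA. It gave 69 for EDL, 1717 for PL (1003 higher, 714 lower) and 57 for GS. Its pairs gave 212 (TA and EDL), 1065 (TA and PL), 172 (TA and GS), 420 (TA and IF), 643 (EDL and PL), 63 (EDL and GS), 94 (EDL and IF), 608 (PL and GS), 835 (PL and IF) and 67 (GS and IF), and 313 entries of the submitters' lists passed. Limma voom with sample weights, which ran from 0.201 for a PL library to 4.92 for an IF library, gave 286 for the 5 pools at once, 1505 for IF, 66 for EDL and 15 for PL. Its pairs gave 28 (TA and EDL), 0 (TA and PL), 625 (TA and IF), 3 (EDL and PL), 54 (EDL and GS), 767 (EDL and IF), 11 (PL and GS), 57 (PL and IF) and 435 (GS and IF), and 319 entries of the submitters' lists passed. For TA and PL, the voom count of 0 stands beside 33 by edgeR, with 1065 by DESeq2.

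With only the 6 libraries of a pair, edgeR gave 2 (TA and EDL), 1 (TA and PL), 4 (TA and GS), 469 (TA and IF), 0 (EDL and PL), 22 (EDL and GS), 403 (EDL and IF), 0 (PL and GS), 7 (PL and IF) and 177 (GS and IF), and 247 entries of the submitters' lists passed. In that setting, the spread is no longer shared with the other pools. For list tests, an estimated correlation left 0 of 18 calls. Fry passed 16 tests, but 7 of these were among the 18 and the others were not. Without PL 2 and PL 3, which leaves PL with 1 library assumed to vary like the other pools, the counts were 10 for PL, 236 for TA, 28 for EDL, 70 for TA and EDL, 39 for TA and GS, 454 for TA and IF, 2 for EDL and PL, 31 for EDL and GS, 68 for EDL and IF, 24 for PL and IF and 77 for GS and IF. List calls were then 11, of which 9 were among the 18, and 245 entries of the submitters' lists passed. For IF the count stayed near, at 156, with 77 higher and 79 lower against 101 and 57.

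Leaving out 1 library at a time gave counts from 66 to 1211 for the 5 pools at once, 31 to 333 for IF, 22 to 246 for TA, 2 to 25 for EDL, 360 to 3210 for PL and 2 to 34 for GS. Pairs ran from 2 to 32 (TA and EDL), 23 to 1800 (TA and PL), 2 to 21 (TA and GS), 36 to 188 (TA and IF), 0 to 1778 (EDL and PL), 3 to 20 (EDL and GS), 15 to 44 (EDL and IF), 6 to 1646 (PL and GS), 22 to 1986 (PL and IF) and 7 to 39 (GS and IF). List calls ran from 12 to 19 and the submitters' lists from 86 to 246. List levels stayed at 0, where the small number of splits left little room for a call.

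Of single named results, 263 passed in the main test and 84 did not, and direction was compared only for the 263. Under the alternatives, 6887 values stayed on their side of the threshold, 1375 no longer passed and 92 newly passed. Another 24 reversed, all of them for PL against the other 4 pools. Without PL 2 and PL 3 these were Crabp1 at -2.78, Isl2 at -0.43, Bcl11b at -1.67, Cdh22 at -0.94, Pcdh1 at -0.47, Sema4b at -0.835, Sema5b at -1.215, Flrt1 at -1.44, Grin3b at -0.13, Gria3 at -1.39, Ucn at -2.81 and Mobp at -0.98 on the log2 scale. Without PL 2 they were Crabp1 at -2.76, Efnb1 at -0.52, Grin3b at -1.06 and Ucn at -2.79, and without PL 3 Bcl11b at -1.415, Sema4b at -0.95, Sema5b at -1.04 and Gria3 at -0.18. Without PL 1 Ntf3 was at -0.18. The highest values of these genes with another library left out were 5.65 for Crabp1, 7.26 for Bcl11b, 9.0 for Efnb1, 3.72 for Sema4b, 3.27 for Sema5b, 6.07 for Ntf3, 5.75 for Grin3b, 2.18 for Gria3 and 7.87 for Ucn. Under voom Crabp1 was at -0.0459, Sema5b at -0.0767 and Gria3 at -0.13.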

Other observations

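The tests of the sparse PL libraries, the subset of splits without them, the tests of all other cell types, and the comparison of GS and IF with TA, EDL and PL and of other joined pools, were chosen only after the result had been seen, the last after the levels of Isl1. Set against TA, EDL and PL, the GS and IF pools together differed in genes beside Isl1, which had 3588 reads in their 6 libraries and 5 in the 9 others. Chrna3, a nicotinic receptor subunit, had 2202 reads against 39, and Camk2a, a calcium-dependent kinase of synapses, was higher by 3.68 ± 0.47 on the log2 scale (standard error, n = 6 and 9). Lower in GS and IF were Sox6 (-3.68 ± 0.40), Plxna2 (-2.76 ± 0.30), Scg2 (-2.51 ± 0.25), Alcam (-2.47 ± 0.22), the synaptic vesicle protein Syp (-1.20 ± 0.22) and the glutamate transporter Slc1a2 (-1.03 ± 0.18). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 6.00e-06 for Alcam, 2.02e-05 for Isl1, 2.26e-05 for Scg2, 5.47e-05 for Plxna2 and Sox6, 0.000339 for Chrna3 and 0.000355 for Camk2a. It called 58 genes, 27 higher and 31 lower, of which 17 had all 6 libraries apart from the 9 others. Of the 58, 45 were also called for IF, 13 for GS and 7 for both. The count was 45 without PL 2 and PL 3, with 34 genes shared, and ran from 22 without IF 1 to 600 without PL 1. Of 100 splits of the 15 libraries into 6 and 9, 1 gave as many, the real one, and the highest other gave 3, but these splits break up the pools and say nothing of which pools are alike. Of the 10 ways to join 2 of the 5 pools 3 gave as many, GS and IF among them, with 104 for TA and PL and 91 for EDL and IF, and without PL 2 and PL 3 the highest other was 99, for TA and GS. The count therefore does not set GS and IF apart from other joined pools, and they were picked for Isl1.

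Xist, transcribed from the inactive X chromosome of females, ran from 1.26 CPM in TA 2 to 379 in GS 2. The Y-linked Ddx3y was at 0 CPM in PL 3 and IF 3 and at 0.170 in GS 2, and between 13.9 in TA 3 and 86.0 in TA 2 elsewhere.

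In PL, 646 genes were called higher and 52 lower. The balance did not hang on the choice among the scalings tried. The share of higher calls was still 91.1% or more under median-of-ratios and upper-quartile scaling. No run without such scaling was made, so a shift that these scalings share stays open. The size of the pattern did move, to 319 higher and 31 lower with upper-quartile scaling. The balance itself was weaker by DESeq2, with 1003 higher and 714 lower, and gone without PL 1, with 1608 and 1602. The values are consistent with PL 2 and PL 3 as a source: with PL 1 exchanged for each of the 12 libraries of other pools in turn, the median share of higher calls was 92.7% (70.2% to 99.1%), and the calls numbered 328 to 1337. That test cannot part the sparseness of PL 2 and PL 3 from a biology they share, and with PL 2 and PL 3 as the only PL libraries the excess was absent. Over the genes called higher, PL 1 reached 0.224 of the mean difference of PL 2 and PL 3, which decides nothing because these genes were picked by the call. The design names a biological difference, the pool itself, which stays open for the genes that PL 1 shares. What made the libraries sparse is given by no label.

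Genes called higher in IF may reflect the greater number of genes detected in its libraries. A line over the 12 other libraries reached 0.100 of the IF difference at the IF share of zeros, with an upper limit of 0.210. The mean level of these genes was 4.93 ± 0.08 in IF and at most 1.80 in another library. Both values rest on genes picked by the call on these same libraries, so they decide nothing and detection stays open. The pool as a biological difference stays open, untested, and a batch of the IF libraries, which no label gives, stays open too.

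Genes called lower in IF could follow a smaller amount of myelin RNA captured with the neurons. Over the 12 other libraries their deviations from the pool means had a median correlation of -0.173 with those of the oligodendrocyte list (quartiles -0.376 to 0.0194, 55 genes outside the list), where the list's own members had 0.451. Less RNA of all other cell types was tested on the astrocyte, microglia and endothelial lists only. It failed there, since 0 of them fell by at least 50% of the oligodendrocyte drop in mean level. But the microglia and endothelial lists could hardly show a fall. Their mean log2 levels were only 0.838 and 1.63 in the 12 other libraries, and the IF libraries had the fewest tested genes at 0. The astrocyte list, at 5.64 in the 12 others and 5.62 in IF, showed no such drop in mean level. By median log2 fold change, not used in that test, IF was at -1.29 for inhibitory interneuron, -0.38 for astrocyte, -0.12 for endothelial and 0.70 for microglia markers. The inhibitory interneuron list, left out of the test, differed by -0.20 in mean level. The lower level of the oligodendrocyte markers themselves, among them Mbp at 68.7 ± 19.6 CPM in IF, stays open between captured myelin and the pool.

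Splits of the 15 libraries into groups of the same sizes, 100 for each comparison, were counted for the calls. For the 5 pools at once 1 split gave as many as the real 188, with 34 the highest other, a share under 0.05. Random groupings of these libraries thus seldom gave that count. The share treats the libraries as exchangeable, while whether they shared animals is not known. For PL 1 gave as many as 698, with 554 the highest other, a share under 0.05. But with PL 1 exchanged for each library of other pools in turn, 6 of 12 groups gave as many, so this share does not exclude chance. PL 2 and PL 3 joined with TA 1 gave 852 in a split for IF, and joined with GS 2 gave 720 in a split for EDL. The PL count thus depends on the 2 sparse libraries. For IF 4 splits gave as many as 158, a share under 0.05, but the highest other gave 852. For TA 8 gave as many as 60 (highest other 467), for EDL 30 as many as 14 (720) and for GS 26 as many as 18 (649), so over all splits chance is not excluded for these counts. The other splits with at least the real count point to a structure of the samples: the 3 for IF held both PL 2 and PL 3 in their group, and 6 of 7 for TA, 29 of 29 for EDL and 25 of 25 for GS held at least 1 of them. The remaining split for TA, with 61 calls, had the 3 IF libraries as its group. Some splits had a group with neither PL 2 nor PL 3, as the real groups of these pools do. Their highest count was 2 over 69 splits for IF, 3 over 59 for EDL and 4 over 53 for GS, all below the real counts. But all splits except the real one also broke up other pools, which can widen the shared spread and lower any count. They thus do not show that the calls of 1 named pool are its own. The 10 splits of a pair are too few for a share under 0.05, and the real split was the 1 with most calls in each. The real and highest other counts were 13 and 0 for TA and EDL, 33 and 25 for TA and PL, 9 and 0 for TA and GS, 90 and 0 for TA and IF, 7 and 0 for EDL and PL, 10 and 0 for EDL and GS, 29 and 0 for EDL and IF, 17 and 13 for PL and GS, 129 and 0 for PL and IF, and 18 and 0 for GS and IF.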
